A study of Mus musculus with 6 samples.

How the data were processed

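The data are 6 samples of primary microglia, the resident macrophages of the brain, from C57/BL6 mice. The titles and the treatment field put 3 samples in a control group and 3 in a group co-cultured with regulatory T cells (Tregs). Per the series design text, the Tregs sat in permeable inserts above brain slices taken 5 days after transient occlusion of the middle cerebral artery (tMCAO, an ischemic stroke model) for 24 hours. The inserts were then moved above the microglia for 2 days. Per the labels' protocols, RNA was extracted with Trizol, cDNA was made with the SMART-Seq HT kit, and libraries were made by tagmentation with Nextera XT. They were sequenced paired-end on an Illumina NextSeq. This cDNA kit amplifies full-length polyadenylated transcripts by PCR without molecular identifiers, so intervals from counts cover counting error only. Whether the counting used strand is not given in the sources used here.

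Per the submitters' processing notes, the tools were STAR (no version given) and HTSeq 0.11.2 with the mouse build GRCm38. The annotation release and the counting options are not given in the sources used here. The authors deposited whole-number read counts per gene, not normalized, in one sheet keyed by Ensembl identifier with 35275 gene rows and in a second sheet keyed by gene name with 35186 rows. Of 35161 names in both sheets, 35133 had equal counts in all samples, and the sheet with identifiers was used. The authors also deposited FPKM values, counts scaled by gene length and library total. In that table the length implied by count, total and FPKM was constant across samples within a relative tolerance of 1e-06 for 12011 of 12011 genes checked, those with at least 10 counts in every sample. The FPKM values therefore come from the same counts, and were used only in alternatives. Spreadsheet software had turned 27 gene names into dates, and these were restored through the identifiers. Of the identifiers, 34490 (97.8%) were in GENCODE M21, a GRCm38 annotation that may differ from the authors' release. It supplied coordinates, which count from 1.

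From the deposited counts, edgeR 4.0.16 (R 4.3.3, limma 3.58.1) gave the gene tests. Genes were kept by filterByExpr with its defaults over the 2 groups, libraries were scaled by TMM (trimmed mean of M values), and dispersions were estimated with the robust option. A robust quasi-likelihood fit (legacy mode) with group as its only term was followed by the two-sided quasi-likelihood F-test. P values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 are called changed. Levels are TMM-scaled CPM, counts relative to the scaled library total, given as mean ± SD with n = 3 per group, and log2 fold changes (co-cultured minus control) come with the SE of the fit.

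Gene lists for 36 pathways, cell types and quality measures (700 entries), the tests, the alternatives and the rule for naming genes were fixed before the data were examined. A list was tested if at least 5 members passed the filter, which 35 did. The test was limma's camera, which compares a list with all other genes, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over the 35 lists. Each list is described by its members called higher or lower over all genes tested and by the count adjusted over the list alone. For 28 of 35 lists both counts were equal, and for the others both are given. After the first results had been seen, 3 listed genes (Adgrg1, Nectin2 and Vsir) that the table names by an older symbol were joined through their identifiers.

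The named genes are the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, passing over predicted, clone-named and pseudogene entries. Added to these are up to 4 members with the smallest adjusted p of each biology list. For lists of other cell types and of sample quality they are the 2 most abundant members and up to 2 with the smallest adjusted p. Spp1 and each tested receptor of the osteopontin list are named whatever their result. Genes whose values or counts are given outside this rule are marked as such, and some genes the rule names are not reported here.

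On counts simulated for this comparison over 13274 genes, the gene test recovered 86.6% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold. It also called 24 genes that had no change. The planted changes were 67, 67 and 66 genes at these sizes, up and down, drawn only from genes above a minimum level. In the data 6752 genes changed, so these rates do not cover that setting or genes at lower levels. A simulated list raised 1.5-fold was called, and 0 of 33 lists without shared genes were. The simulated genes varied independently, whereas the estimated inter-gene correlation in the data was 0.759 for ribosomal proteins and 0.534 for interferon-stimulated genes. The simulation therefore cannot show how often camera calls a list of correlated genes wrongly. Alternatives covered other scalings, DESeq2 1.42.0, limma-voom, the newer edgeR fit, filters, a stricter threshold, a test against a 1.5-fold change and the FPKM table with pseudocounts of 1 and 0.1. They also included the replicate number as a block, each sample left out in turn and other list tests. The count of near-identical genes depends on how the authors' counting treated reads that match several genes, which the sources used here do not give. Values of the Ifit, Oas, Gbp, Slfn, Apol9, Tgtp and H2-Q families, of ribosomal proteins with many pseudogenes, and of mitochondrial genes with nuclear copies are therefore uncertain.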

Results

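RNA from 6 samples of primary mouse microglia was sequenced, 3 kept as controls and 3 co-cultured for 2 days with Tregs that had first spent 24 hours above brain slices from mice 5 days after tMCAO. Tregs are T cells that restrain immune responses. The comparison asks how such Tregs, acting through a permeable insert, change gene expression in microglia, and the series title names osteopontin, repair of white matter and stroke. No slice exposure is recorded for the controls. Effects of the Tregs therefore cannot be told apart from those of slice material carried with the insert, or of the insert itself. The deposited totals were 21465960, 16972758 and 21431220 counts in the control libraries and 22084542, 21531638 and 20987384 counts in the co-cultured libraries. On average 18110 ± 340.4 genes had a count in the controls and 18080 ± 183.8 in the co-cultured libraries (SD, n = 3). Pearson correlations of log2 CPM across genes were 0.9914 to 0.993 within groups and 0.9601 to 0.9648 between groups. The first principal component held 76.5% of the variance. Counts of same-group pairs differed by more than sampling noise, with a chi-square per gene between 3.03 and 8.91, so no library was a copy of another. Nothing in the labels says that the replicates came from separate animals or cultures, so p values measure only the spread between these samples, which may be technical.

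Microglia exposed to Tregs carried more transcript of interferon-stimulated genes, of most chemokines tested and of the receptors Marco and Fpr1, and less of most disease-associated microglia genes. The adjusted p values of these 3 lists were 3.44e-19, 1.27e-04 and 0.00242 with limma's camera, and 0.384, 0.384 and 0.633 with an estimated correlation. Marco, a scavenger receptor, rose from 2.82 ± 1.13 to 126 ± 11.4 CPM (mean ± SD, n = 3 per group here and throughout), 44.9-fold with an adjusted p of 3.75e-08. Ms4a4c, a membrane-spanning protein of the Ms4a family, rose from 1.66 ± 0.439 to 132 ± 12.1 CPM (79.2-fold). Itgax, which encodes the integrin CD11c, fell from 195 ± 7.796 to 6.92 ± 1.01 CPM, 28.2-fold lower (adjusted p = 1.97e-30). Of 13274 genes tested, 6752 changed, 3432 higher and 3320 lower in the co-cultured microglia. At least a 2-fold change was seen in 668 of the genes that rose and 652 of those that fell, and at least a 4-fold change in 231 and 122. The groups did not overlap at 7589 genes (57.2%), where chance gives 10%. The balance of directions depends on scaling: 50.8% of changed genes were higher with TMM, 40% with upper-quartile scaling (2731 higher, 4090 lower) and 41% with library totals alone (2774 higher, 3997 lower). The share was 41.6% in the FPKM table (2515 higher, 3536 lower). Tested against a 1.5-fold change, 1500 genes were called.

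The 10 largest rises were those of Slfn4, Slfn1, Arg1, Ms4a4c, Apol9b, Fpr1, Tgtp2, Marco, Ppbp and Ccl7. Slfn4 (chromosome 11, 83175186 to 83190216, plus strand), a member of the interferon-inducible schlafen family, had 1 count over the control libraries and 871 over the co-cultured ones. The control count was in replicate 2, and without that library the log2 fold change of Slfn4 went from 9.27 to 11.20. The ratio was 807 with a 95% counting interval of 144.5 to 31920. Its neighbour Slfn1 (chromosome 11, 83116849 to 83122670, plus strand) rose from 0.103 ± 0.0912 to 14.7 ± 1.12 CPM. Arg1, arginase 1, an enzyme that consumes arginine and marks alternatively activated macrophages, rose from 0.618 ± 0.0355 to 50.9 ± 22.7 CPM (chromosome 10, 24915221 to 24927484, minus strand). Its co-cultured libraries varied widely and its adjusted p of 0.00212 became 0.0525 with limma-voom, the highest of 16 alternatives (lowest 2.01e-37). Fpr1, a receptor for bacterial and mitochondrial formyl peptides, rose from 0.274 ± 0.162 to 14.8 ± 1.44 CPM, and Apol9b rose from 0.107 ± 0.147 to 6.48 ± 1.08 CPM, with 7 counts over the control libraries and 409 over the co-cultured ones. Without control replicate 3 the log2 fold change of Apol9b went from 5.75 to 7.68 and that of Slfn1 from 7.14 to 6.53, and without control replicate 1 that of Fpr1 went from 5.71 to 6.33. The platelet-type chemokine Ppbp rose 37.97-fold and the monocyte chemoattractant Ccl7 29.9-fold, both with large spread between the co-cultured libraries (21.1 ± 8.96 and 65.1 ± 21.4 CPM). Tgtp2, an interferon-gamma-induced GTPase, rose 47.4-fold.

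The 10 largest falls were those of Baiap2l2, Itgax, Mamdc2, Scml4, Pld5, Cbfa2t3, Postn, Mgll, Sardh and Ppp1r3c. Itgax lies on chromosome 7, 128129547 to 128150657, plus strand. Mamdc2 (chromosome 19, 23302609 to 23448442, minus strand) fell from 184 ± 4.35 to 8.49 ± 1.11 CPM, 21.6-fold. Mgll, monoacylglycerol lipase, which breaks down the endocannabinoid 2-arachidonoylglycerol, fell from 70.3 ± 2.73 to 5.28 ± 1.02 CPM. Postn, the matrix protein periostin, fell from 38.8 ± 2.31 to 2.68 ± 0.174 CPM. Sardh, a mitochondrial sarcosine dehydrogenase, fell 12.6-fold, and Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, 11.6-fold. Baiap2l2 fell from 5.02 ± 0.597 to 0.144 ± 0.146 CPM, with a log2 fold change of -5.08 that became -6.04 without co-cultured replicate 3. Scml4, Pld5 and Cbfa2t3 were between 15.8-fold and 20.6-fold lower. As the naming rule required, the groups did not overlap at any of these 20 genes.

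**Figure D1:**
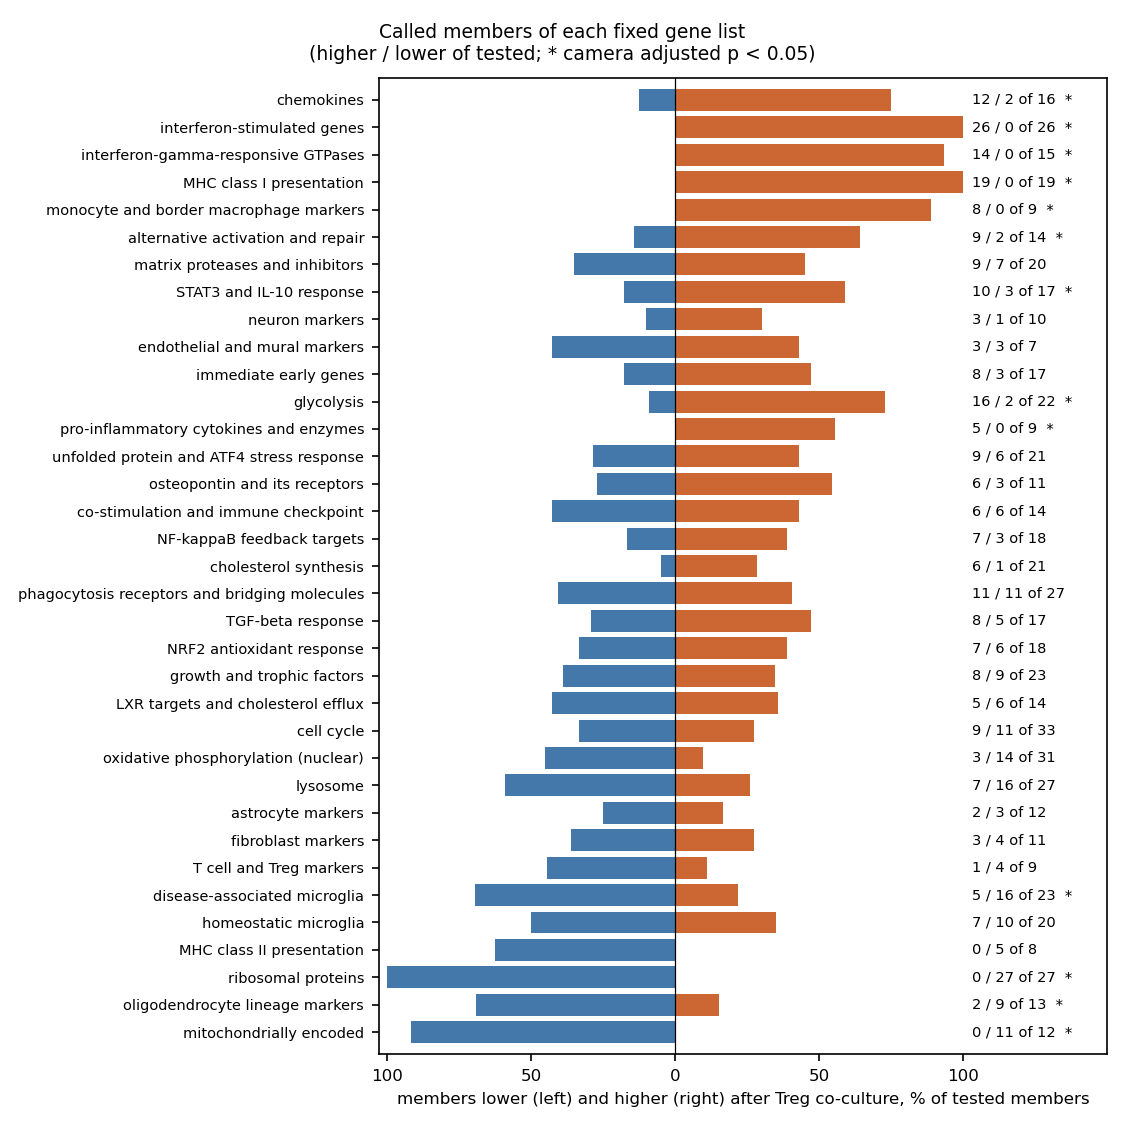
Each bar gives, for one gene list fixed in advance, the percentage of tested members called higher (orange, right) or lower (blue, left) in Treg co-cultured microglia, with the counts printed at the right and an asterisk where limma's camera gave an adjusted p below 0.05. All 26 interferon-stimulated genes were higher and all 27 ribosomal protein genes were lower.

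All 26 tested interferon-stimulated genes rose, with a median log2 fold change of 2.51. Ifitm3, which restricts virus entry, rose from 45.3 ± 1.59 to 364 ± 21.4 CPM (8.03-fold). Oas2, a sensor of double-stranded RNA, rose 6.16-fold to 275 ± 11.99 CPM, Ifit1 7.68-fold to 237 ± 12.5 CPM, and Stat2, a transducer of type I interferon signals, from 212 ± 7.44 to 914 ± 58.02 CPM. The list's adjusted p from camera was 3.44e-19, and 0.384 with an estimated correlation. Among interferon-gamma-responsive GTPases, 14 of 15 rose and 1 was not called (median log2 fold change 2.24). Iigp1 went from 2.75 ± 0.588 to 73.3 ± 5.59 CPM, Gbp6 from 3.94 ± 0.852 to 65.4 ± 0.259 CPM and Gbp9 from 36.03 ± 2.54 to 134 ± 3.98 CPM. The adjusted p was 4.53e-10, and 0.384 with an estimated correlation. In the same libraries the mitochondrial share of counts was 0.700%, against 1.36% in controls, the ribosomal protein share was 1.27%, against 1.96%, and 8 of 9 monocyte and border macrophage markers were higher.

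MHC class I presentation genes rose. All 19 tested class I members rose, with a median log2 fold change of 1.01 (adjusted p = 3.46e-11, and 0.384 with an estimated correlation). H2-T22 rose from 78.3 ± 4.905 to 307 ± 7.37 CPM and Tap1, a peptide transporter of the endoplasmic reticulum, from 117 ± 8.96 to 369 ± 1.95 CPM. The near-identical H2-Q6 and H2-Q7 rose 12.2-fold and 7.45-fold. In the same libraries the mitochondrial share of counts was 0.700%, against 1.36% in controls, the ribosomal protein share was 1.27%, against 1.96%, and 8 of 9 monocyte and border macrophage markers were higher. No class II member of 8 tested rose and 5 fell, with a median log2 fold change of -0.54, and the list was not called (adjusted p = 0.0684). It passed the threshold without control replicate 1 (0.0341) and without control replicate 2 (0.045), with a range of 0.00179 to 0.384 over its 12 alternatives. Cd74, the class II invariant chain, fell from 13.2 ± 0.84 to 9.298 ± 0.832 CPM, H2-DMa from 4.91 ± 0.499 to 3.33 ± 0.317 CPM, and Ifi30, a lysosomal thiol reductase, from 108 ± 7.66 to 52.3 ± 3.59 CPM. Of 14 co-stimulation and checkpoint genes, 6 rose and 6 fell (6 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.544). Cd274, which encodes the checkpoint ligand PD-L1, rose from 48.2 ± 2.24 to 129 ± 7.99 CPM, and Lgals9, a ligand of the checkpoint receptor TIM-3, from 134 ± 11.4 to 332 ± 9.31 CPM. The co-stimulatory receptor Cd40 rose 7.61-fold to only 3.99 ± 0.923 CPM.

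Most disease-associated microglia genes, the set that microglia raise near plaques and in demyelination, were lower after Treg co-culture. Of 23 tested, 16 fell, 5 rose and 2 were not called, with a median log2 fold change of -0.42. Besides Itgax, the beta-glucan receptor Clec7a fell from 532 ± 10.96 to 114 ± 8.796 CPM and the tetraspanin Cd9 from 157 ± 6.57 to 56.1 ± 3.66 CPM. Axl, a receptor for apoptotic cells, went the other way, from 120.2 ± 1.47 to 286 ± 20.4 CPM. The list had an adjusted p of 0.00242, and 0.633 with an estimated correlation. Homeostatic microglia genes were split, 7 higher and 10 lower of 20 (median log2 fold change -0.47), and the list was not called (adjusted p = 0.197). Gpr34, a lysophosphatidylserine receptor, fell from 75.8 ± 1.57 to 21.6 ± 2.81 CPM, Fcrls from 994 ± 40.3 to 550.0 ± 40.5 CPM, and Tgfbr1, a receptor of TGF-beta, from 242 ± 9.32 to 136 ± 3.96 CPM. In the same co-cultured libraries the mitochondrial share of counts was 0.700%, against 1.36% in controls, and the ribosomal protein share was 1.27%, against 1.96%. In them 8 of 9 monocyte and border macrophage markers were higher. Mbp, from the oligodendrocyte lineage list, was at 66.3 ± 1.57 CPM there, against 104 ± 3.85 in controls.

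Lysosome genes were not called as a list (adjusted p = 0.065), with 16 of 27 lower and 7 higher. The list passed the threshold without control replicate 1 (0.0341) and in the FPKM table (0.0486), with a range of 5.37e-04 to 0.653 over its 12 alternatives. Atp6v0d2, a subunit of the lysosomal proton pump, fell from 297 ± 1.45 to 60.1 ± 0.547 CPM, Hexa from 1759.8 ± 65.5 to 848 ± 13.1 CPM and Gusb from 1269 ± 30.1 to 644 ± 26.5 CPM. The protease Ctsc rose from 357 ± 13.6 to 1101 ± 17.1 CPM. Phagocytosis receptors and bridging molecules were evenly split, with 11 higher and 11 lower of 27 (adjusted p = 0.544). Complement C3 rose from 108 ± 1.88 to 713 ± 47.6 CPM, the scavenger receptor Msr1 from 324 ± 10.6 to 868 ± 50.7 CPM and the high-affinity Fc receptor Fcgr1 from 245 ± 25.3 to 1389.7 ± 68.8 CPM. Mfge8, which bridges phosphatidylserine on dying cells to integrins, fell from 320.5 ± 11.2 to 96.5 ± 5.01 CPM.

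Spp1, which encodes osteopontin, was already abundant and rose further, from 4019 ± 208 to 7217 ± 739 CPM (1.796-fold, log2 fold change 0.84 ± 0.06 SE, adjusted p = 7.58e-12). It lies on chromosome 5, 104435118 to 104441050, plus strand, and the groups did not overlap. The integrin subunits that bind osteopontin moved in both directions. Itgav rose from 170.1 ± 7.26 to 375 ± 40.7 CPM (adjusted p = 1.17e-12) and Itga9 from 55.9 ± 2.67 to 139 ± 12.5 CPM (adjusted p = 9.05e-18). The hyaluronan and osteopontin receptor Cd44 rose from 392 ± 4.63 to 597 ± 11.1 CPM, Itga5 from 183 ± 3.28 to 247 ± 11.1 CPM and Itgb1 from 747 ± 7.75 to 856 ± 18.5 CPM. Itgb3, a partner of Itgav, fell from 53.1 ± 4.599 to 7.48 ± 1.35 CPM (7.101-fold lower, adjusted p = 4.39e-19), and Itgb5 fell from 943 ± 4.43 to 781 ± 47.7 CPM.

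Itgb8 was near the floor at 2.17 ± 0.828 and 1.11 ± 0.393 CPM. Its adjusted p of 0.0103 became 0.0658 without control replicate 1, 0.0567 without control replicate 3 and 0.0573 without co-cultured replicate 3, over a range of 0.0013 to 0.0658 in 15 alternatives. Itga4 had 121 ± 13.5 CPM in controls and 110.2 ± 9.06 CPM after co-culture (adjusted p = 0.132). It passed the threshold without control replicate 3 (0.00223), without co-cultured replicate 1 (0.0289), with upper-quartile scaling (0.023), with library totals alone (0.0301) and with no filter (0.0304), in each case lower after co-culture, and its adjusted p over 16 alternatives ranged from 0.00223 to 0.455. Itga8, at 0.645 ± 0.103 and 0.475 ± 0.0918 CPM, was not called (adjusted p = 0.454). Of 11 tested members of the osteopontin list, 6 rose and 3 fell, and the list was not called (adjusted p = 0.328). Its median log2 fold change was 0.20 and its mean -0.0096, of opposite sign.

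**Figure D2:**
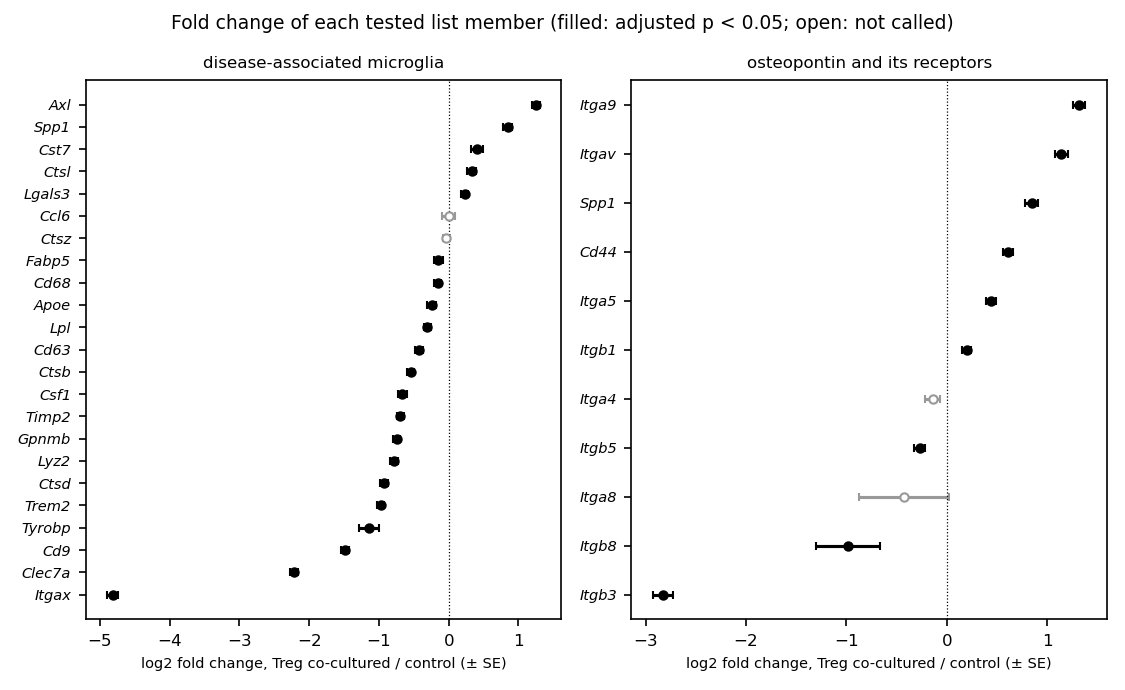
Points give the log2 fold change (co-cultured minus control) of each tested member of the disease-associated microglia list (left) and the osteopontin list (right), with bars for the SE of the edgeR fit; filled points had an adjusted p below 0.05 and open points did not. Spp1 is in both lists and was higher, while Itgax and Itgb3 were the lowest members.

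Genes of alternative activation and repair rose as a list, with 9 of 14 tested members higher and 2 lower (median log2 fold change 0.79, adjusted p = 0.00199, and 0.384 with an estimated correlation). The list was fixed with 19 members. Retnla, Chil3, Pdcd1lg2, Cd163 and Il10, named here after their values were seen, did not pass the filter. Retnla had 0 counts in every library, and Chil3 had 2 in control replicate 1 and 0 elsewhere. Pdcd1lg2 had 2, 0 and 2 counts in controls and 0, 0 and 2 after co-culture. Cd163 had 2, 1 and 0, against 4, 9 and 1, and Il10 had 3, 1 and 6, against 6, 9 and 9. Il4ra, the interleukin-4 receptor chain, rose from 178 ± 2.45 to 721 ± 45.3 CPM. The mannose receptor Mrc1 rose from 270.4 ± 7.14 to 448 ± 23.1 CPM and the interleukin-1 receptor antagonist Il1rn from 25.6 ± 2.42 to 50.9 ± 3.78 CPM. Arg1, Marco and Msr1 also belong to this list, and Mrc1 is also a border macrophage marker. In the same libraries 8 of 9 monocyte and border macrophage markers were higher (adjusted p = 5.89e-04, and 0.384 with an estimated correlation), the mitochondrial share was 0.700% of counts, against 1.36% in controls, and the ribosomal protein share 1.27%, against 1.96%. The STAT3 and IL-10 response list, which shares Il4ra, had 10 members higher and 3 lower of 17 (adjusted p = 0.00467, and 0.523 with an estimated correlation). Stat3 rose from 149 ± 2.94 to 316 ± 11.7 CPM and Sbno2 from 197 ± 7.14 to 409 ± 11.7 CPM.

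Most chemokines rose, 12 of 16 higher and 2 lower, with a median log2 fold change of 2.80 (adjusted p = 1.27e-04, and 0.384 with an estimated correlation). Ccl12 rose from 1.301 ± 0.128 to 36.8 ± 6.28 CPM and Ccl5, a T cell attractant, from 2.24 ± 0.608 to 30.4 ± 2.24 CPM. Cxcl10, an interferon-induced ligand of CXCR3, rose from 1.79 ± 0.489 to 20.1 ± 3.85 CPM, and the abundant Ccl9 from 398 ± 10.1 to 721 ± 65.6 CPM. Of 9 pro-inflammatory cytokines and enzymes tested, 5 rose and 0 fell (adjusted p = 0.0214, and 0.384 with an estimated correlation). Among them were the prostaglandin enzymes Ptges, from 4.05 ± 1.39 to 22.7 ± 1.95 CPM, and Ptgs2, from 4.89 ± 1.42 to 13.3 ± 1.504 CPM, the cytokine Il18, from 5.68 ± 0.246 to 14.3 ± 0.779 CPM, and the NADPH oxidase subunit Cybb, from 1511 ± 29.6 to 1851 ± 62.8 CPM. NF-kappaB feedback targets were not called as a list (7 higher, 3 lower of 18, adjusted p = 0.324). Bcl3 rose from 15.8 ± 2.25 to 35.8 ± 2.49 CPM, while Tnfaip2 fell from 192 ± 5.403 to 131 ± 1.57 CPM. The same co-cultured libraries had a lower mitochondrial share of 0.700% (1.36% in controls), a lower ribosomal protein share of 1.27% (1.96% in controls) and higher levels of 8 of 9 monocyte and border macrophage markers.

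**Figure D3:**
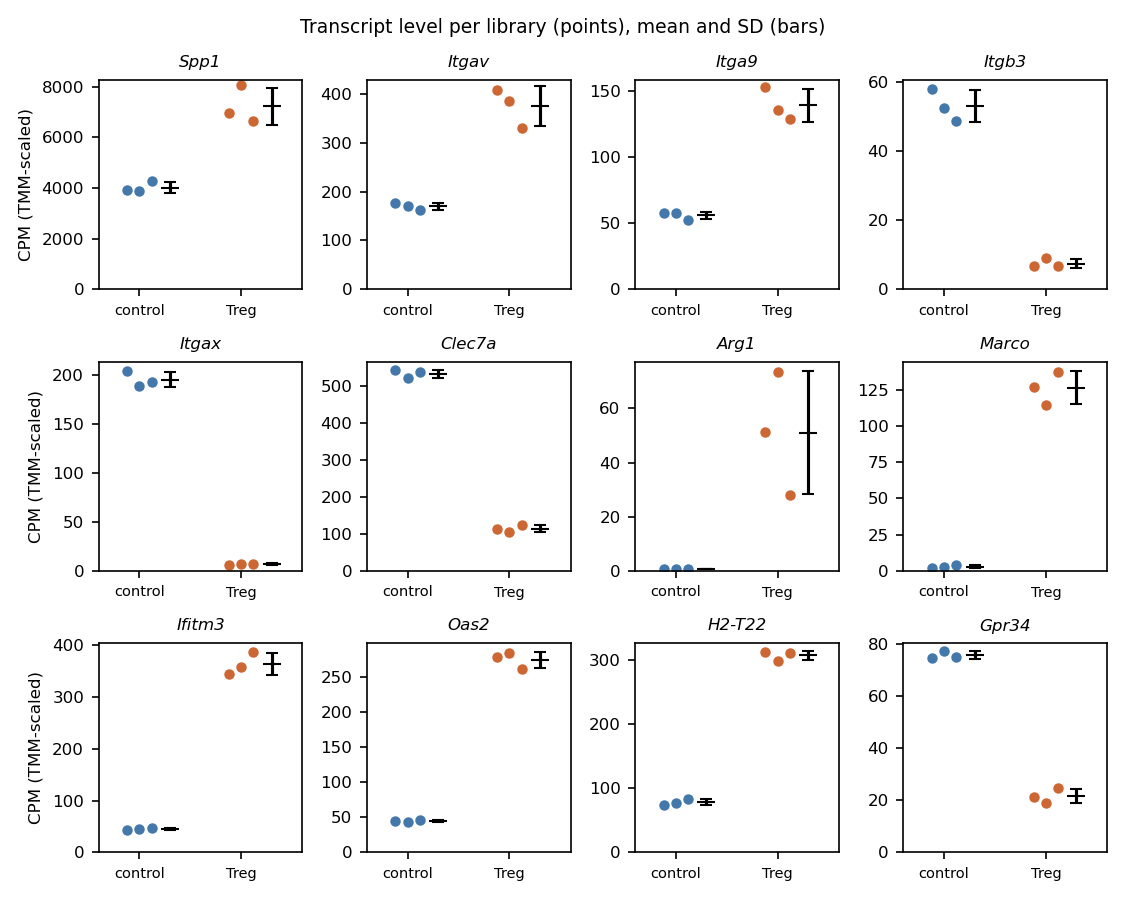
Points give the level of 12 named genes in each library in TMM-scaled CPM on linear axes from 0 (control blue, Treg co-cultured orange), and the bar beside each group gives mean and SD (n = 3). Each of the 12 genes separated the groups without overlap, and Arg1 had the widest relative spread among the co-cultured libraries of these genes.

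Secreted growth and matrix factors changed in both directions. Vegfa, an angiogenic factor, rose from 22.1 ± 1.897 to 86.3 ± 8.48 CPM, Tgm2, a transglutaminase, from 32.2 ± 4.61 to 236 ± 18.6 CPM, Pdgfc from 9.897 ± 0.916 to 24.01 ± 1.68 CPM and Fgf1 from 2.98 ± 0.245 to 10.5 ± 0.805 CPM. Of 23 growth and trophic factors, 8 rose and 9 fell, and the list was not called (adjusted p = 0.824). Among matrix proteases and inhibitors, 9 rose and 7 fell of 20 (9 and 8 adjusted over the list alone), also not called (adjusted p = 0.815). The gelatinase Mmp9 fell from 63.6 ± 4.297 to 6.81 ± 0.179 CPM, while the membrane protease Mmp14 rose from 67.8 ± 7.32 to 219 ± 9.03 CPM, Adam8 from 2405 ± 48.99 to 4459 ± 205 CPM and Mmp3 from 0.324 ± 0.0395 to 5.89 ± 1.25 CPM. TGF-beta response genes had 8 higher and 5 lower of 17 (adjusted p = 0.451). Tgfbi rose from 31.8 ± 2.53 to 194 ± 15.3 CPM and Bhlhe40 fell from 25.1 ± 1.104 to 10.2 ± 0.852 CPM. The medians of the growth factor, TGF-beta and phagocytosis lists (0.03, 0.06 and 0.06) turned negative with upper-quartile scaling and with library totals.

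Most glycolysis genes rose, 16 of 22 higher and 2 lower, with a median log2 fold change of 0.35 (adjusted p = 5.06e-04, and 0.523 with an estimated correlation). Pkm, pyruvate kinase, rose from 2047 ± 54.2 to 4375 ± 172 CPM, Ldha, lactate dehydrogenase A, from 514 ± 18.8 to 983 ± 38.4 CPM, and Tpi1 and Pgk1 rose 1.85-fold and 1.76-fold. The co-cultured libraries that gave these values had a mitochondrial share of 0.700% (1.36% in controls), a ribosomal protein share of 1.27% (1.96%) and higher levels of 8 of 9 monocyte and border macrophage markers. Nuclear genes of oxidative phosphorylation were 14 lower and 3 higher of 31 (14 and 4 adjusted over the list alone) and not called as a list (adjusted p = 0.145). Cox4i1 fell from 165 ± 15.9 to 99.1 ± 7.73 CPM and Ndufa4 from 42.7 ± 2.59 to 28.4 ± 1.77 CPM. Cholesterol synthesis genes (6 higher and 1 lower of 21, 5 and 1 adjusted over the list alone, adjusted p = 0.203) were not called. Of these, Srebf2, a transcription factor of sterol synthesis, rose from 122 ± 5.68 to 172 ± 10.1 CPM and the reductase Dhcr7 fell from 38.3 ± 2.75 to 24.9 ± 2.405 CPM. LXR targets and cholesterol efflux genes (5 higher, 6 lower of 14, adjusted p = 0.815) had a median of -0.02 and a mean of 0.07. Nr1h3, which encodes LXR-alpha, rose from 4.09 ± 0.372 to 15.7 ± 0.734 CPM and Plin2, a lipid droplet coat protein, from 2534 ± 101 to 3416 ± 31.6 CPM.

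Stress and proliferation lists were not called. The unfolded protein and ATF4 list had 9 higher and 6 lower of 21 (11 and 7 adjusted over the list alone, adjusted p = 0.324). Its regulator Atf4 rose from 83.7 ± 5.695 to 157 ± 3.77 CPM and asparagine synthetase Asns from 14.5 ± 1.29 to 33.5 ± 2.61 CPM. NRF2 antioxidant genes (7 higher, 6 lower of 18, adjusted p = 0.888) had a median near 0 that turned negative with upper-quartile scaling and with library totals. Among them Gsr rose from 78.3 ± 3.26 to 129 ± 14.1 CPM and Gstm1 fell from 27.1 ± 0.712 to 15.7 ± 2.56 CPM. Of 33 cell cycle genes, 9 rose and 11 fell (adjusted p = 0.88). The replication helicase subunits Mcm5, Mcm6 and Mcm2 rose 2.05-fold, 1.93-fold and 1.68-fold, while Cenpa, a centromeric histone, fell from 51.7 ± 1.71 to 11.8 ± 0.897 CPM. Immediate early genes, which respond within minutes to handling or stimulation, had 8 higher and 3 lower of 17 (8 and 5 adjusted over the list alone, adjusted p = 0.22). Their median was 0.39 and their mean -0.05, of opposite sign. Fos rose from 71.5 ± 4.895 to 160.5 ± 5.13 CPM and Zfp36 from 109 ± 6.32 to 201 ± 7.38 CPM. Atf3, the most abundant member, was at 305 ± 15.5 and 282 ± 12.6 CPM and not called (adjusted p = 0.0629). It passed the threshold, lower after co-culture, without control replicate 1 (0.036), without co-cultured replicate 1 (0.0307), with upper-quartile scaling (0.00256), library totals (0.00316), the strict filter (0.0495) and the FPKM table (0.0128), with a range of 0.00256 to 0.234 over 16 alternatives. The 3 early growth response genes of the list, singled out after their values were seen, fell (median log2 fold change -2.70).

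Among the quality measures, ribosomal protein transcripts and transcripts of the mitochondrial genome were lower after co-culture. All 27 ribosomal protein genes tested fell, with a median log2 fold change of -0.58 (adjusted p = 2.41e-09, and 0.523 with an estimated correlation). Rplp0 fell from 702 ± 37.8 to 461 ± 42.4 CPM and Rpl32 from 351 ± 17.4 to 200.3 ± 13.7 CPM. The share of ribosomal protein counts was 1.96% ± 0.107 in controls and 1.27% ± 0.0931 after co-culture. Of 12 mitochondrially encoded genes, 11 fell over all genes and 12 adjusted over the list alone (median -1.01, adjusted p = 3.21e-06, and 0.384 with an estimated correlation). mt-Co1 fell from 6216 ± 206 to 4019 ± 405 CPM and mt-Cytb from 1520.4 ± 70.4 to 517 ± 37.4 CPM. The mitochondrial share of counts was 1.36% ± 0.0344 in controls and 0.700% ± 0.0683 after co-culture. The 10 most abundant genes took 11.96% ± 0.352 and 9.18% ± 0.0862 of counts (SD, n = 3).

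Markers of other brain and blood cells did not move as one. The oligodendrocyte lineage list fell, with 9 of 13 lower and 2 higher (median -0.65, adjusted p = 0.0144, and 0.418 with an estimated correlation). Myelin basic protein Mbp fell from 104 ± 3.85 to 66.3 ± 1.57 CPM and Cspg4 from 127 ± 9.37 to 98.9 ± 7.18 CPM, whereas Cnp, a myelin enzyme also made by other cells, rose from 53.8 ± 3.78 to 129 ± 2.53 CPM. Monocyte and border macrophage markers rose, 8 of 9 (adjusted p = 5.89e-04, and 0.384 with an estimated correlation). Ms4a7 rose from 439 ± 21.8 to 568 ± 27.4 CPM and Folr2 from 28.5 ± 2.95 to 52.6 ± 0.648 CPM. The list shares Mrc1 with the alternative activation list, and its monocyte gene Ccr2, named after its value was seen, was at 1.52 ± 0.375 and 1.51 ± 0.103 CPM.

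The remaining cell type lists were not called. Of 12 astrocyte markers, 2 rose and 3 fell (adjusted p = 0.431). Aqp4 fell from 10.1 ± 1.11 to 2.73 ± 0.627 CPM, Aldh1l1 rose from 11.3 ± 1.43 to 20.1 ± 2.24 CPM, and Gfap was at 6.004 ± 2.25 and 7.86 ± 1.23 CPM (adjusted p = 0.209, 0.0183 without control replicate 1 and 0.0393 with no filter, with a range of 0.0183 to 0.601 over 16 alternatives). Of 10 neuron markers, 3 rose and 1 fell (adjusted p = 0.304), all at low levels, such as Map2 at 3.64 ± 0.79 and 6.87 ± 0.846 CPM. Endothelial and mural markers were 3 higher and 3 lower of 7 (adjusted p = 0.822), with the VEGF receptor Kdr higher (6.21 ± 0.472 to 33.7 ± 3.51 CPM) and the VEGF receptor Flt1 lower (95.6 ± 5.75 to 47.02 ± 4.46 CPM). Fibroblast markers were 3 higher and 4 lower of 11 (adjusted p = 0.769), with fibronectin Fn1 rising from 600.2 ± 22.5 to 1021 ± 58.2 CPM. The neutrophil and B cell list had too few members above the filter to be tested.

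T cell receptor transcripts were scarce in both groups. Of 9 T cell and Treg markers, 1 rose and 4 fell (adjusted p = 0.353). Cd28 fell from 119 ± 8.39 to 42.7 ± 2.72 CPM, and Cd4 rose from 2.53 ± 0.726 to 6.41 ± 0.178 CPM. Some T cell genes are named here after their values were seen. Cd3e had 0 counts in the control libraries together and 15 in the co-cultured ones, and Trac had 0 in all 6, where a count of 0 allows up to 3 counts per library. Counts assigned to Foxp3, the defining Treg transcription factor, were 3.22 ± 0.313 CPM in controls and 1.63 ± 0.194 CPM after co-culture. Foxp3 (chromosome X, 7573644 to 7595245, plus strand) overlaps Ppp1r3f (chromosome X, 7557296 to 7574283, minus strand), so its counts are uncertain.

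The authors' count sheet by gene name also carried a list of 134 gene names, mostly surface receptors, with no stated rule of selection. All 134 were tested here, and 132 were higher, 0 were lower and 2 were not called, with 58 at least 2-fold higher. This list may have been chosen on these samples, so its count is not independent evidence of a direction.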

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

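The call of 6752 changed genes stayed within 1.5 times under 19 of 20 alternatives, from 5371 at an adjusted p below 0.01 to 6821 with upper-quartile scaling. Against a 1.5-fold change, 1500 genes were called (809 higher, 691 lower), since this test asks for a larger change. In each alternative with a count of shared calls, from 5205 to 6723 of the main calls were shared, and 0 changed direction. Leaving out one library at a time gave 6028 to 6455 genes. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.033, -0.023 and -0.027. With the replicate block, 6755 genes were called, with 3448 higher and 3307 lower, and 14 lists, all 13 of the main lists and MHC class II presentation (adjusted p = 0.0296, lower). The block also brought Itga4 past the threshold (0.0403). The 13 lists were all called with library totals, the strict filter, each library left out (13 to 15 lists) and the FPKM table (14, with the lysosome list). With an estimated inter-gene correlation camera called 0 lists, with 3 at an unadjusted p under 0.05. The adjusted p of the 13 lists was then 0.384 to 0.633, and their smallest unadjusted p was 0.03. The alternative activation list was lost too, from an unadjusted camera p of 5.12e-04. Its estimated correlation was 0.0196, near the preset 0.01, so a larger correlation hardly accounts for the loss of this list. For the other lists the cause was not tested. Their loss with an estimated correlation therefore does not by itself show that correlation between genes removed the calls. The self-contained test fry called 30 lists, which asks only whether a list's genes move one way on balance. Of 149 named genes, 144 were called. No alternative reversed one, and 8 changed their call in at least one: Arg1 with limma-voom (0.0525), H2-Ab1, Atf3, Ikzf2, Gfap, Stmn2, Itga4 and Itgb8. H2-Ab1, Ikzf2, Gfap, Stmn2 and Itgb8 had means below 10 CPM in both groups.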

Other observations

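Beyond the fixed lists, 14 gene families that partly overlap them were looked at after the results had been seen. All 8 tested schlafen genes rose, with a median log2 fold change of 1.95, as did all 9 Ms4a genes (median 1.26). Of 8 Ifi200 and Pydc genes, a family with sensors of cytosolic DNA, 7 rose and 0 fell (median 3.16). Of 10 Toll-like receptors, 7 rose and 1 fell, and of 8 purinergic receptors 6 rose and 0 fell. All 6 subunits of the MCM replication helicase rose (median 0.62) and 7 of 14 histone genes rose with 0 falling. The 3 tested early growth response genes fell (median -2.70), as did 7 of 13 cathepsins with 3 rising and 8 of 17 subunits of the lysosomal proton pump with 2 rising. Of 10 Slc7 amino acid transporters, 6 rose and 0 fell. Both tested formyl peptide receptors rose (median 5.25). The Fc receptors (2 higher and 2 lower of 6) and the lipid droplet genes of the Plin and Hilpda names (2 higher and 1 lower of 5) had no common direction. No family was tested as a set, and 0 of the 14 medians changed sign with another scaling.

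The tests of myelin transcripts and of the interferon genes, and the closer length match, were chosen after the results were seen; the other tests of length, base composition, scaling and sample splits were not. Among the 10 ways to split the 6 libraries into 3 and 3, only the real one, 1 split, reached 6752 genes, and the highest other gave 0. For lists also only 1 reached 13, and the highest other gave 9. With 10 splits no share below 0.1 is possible, so these splits are too few for a share under 0.05. Every other split mixes control and co-cultured libraries, so the treatment difference widens the spread within its groups. Their counts are therefore not a chance level.

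Ribosomal protein and mitochondrially encoded transcripts fell in 27 of 27 and 11 of 12 genes (median log2 fold change over all 39, -0.68). Other genes matched on length and expression had a median of 0.075 (95% bootstrap interval 0.0171 to 0.133), though they were longer (median length 1502 against 1094 bases). With matches within 10% of the length of 37 members (median 1142 against 1120 bases) the median was 0.11 (interval -0.0614 to 0.154). Genes matched on GC content and expression had a median of 0.0978 (0.0699 to 0.137), which with the length matches argues against a length or base composition bias, and the scaling that lowered the members least still gave -0.672. What also stays open is a lower yield or stability of these transcripts in the co-cultured wells, or a change in the cells' energy and protein synthesis programmes with the Tregs. Neither was tested.

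Most oligodendrocyte-lineage genes tested were lower in the co-cultured libraries. Mbp, whose cell of origin was not tested, fell from 104 ± 3.85 to 66.3 ± 1.57 CPM. Of 11 further oligodendrocyte genes with at least 10 control counts, 10 were lower in every co-cultured library than in every control library, with a median log2 ratio of -3.67 over all 11. Aspa, the remaining gene, was higher. These 11 genes were near the floor, with control means of 0.176 to 3.45 CPM. Fa2h and Gjb1 had 0 co-cultured counts, so their ratios, taken with 3 counts in place of 0, are bounds. Ppp1r14a had 1 count in control replicate 2 and 1 in co-cultured replicate 2, set apart only by the library totals. The fixed list was less uniform: Mbp and Cspg4, its most abundant members in controls, fell by log2 fold changes of only -0.65 and -0.36, and 2 of its 13 members rose, Cnp (1.26) and Pdgfra (1.91, from 0.484 ± 0.0741 to 1.86 ± 0.577 CPM). The falls are consistent with less RNA from oligodendrocyte-lineage cells in the co-cultured wells, which would not explain the rises. Whether all non-microglial cells were fewer stays open: the astrocyte list had a median of -0.21 and the neuron list 0.453, but only 3 and 1 of their members reached 5 CPM, and Nefl and Nefm, neuron markers below the filter, had fewer counts in the co-cultured libraries. Aspa, Fa2h, Gjb1, Ppp1r14a, Pdgfra, Nefl and Nefm were named after their values were seen. No purity sort is stated in the sources used here.

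Interferon-stimulated genes rose without a rise of MHC class II, whose list had a median log2 fold change of -0.536. Interferon gamma usually raises class II genes, but 14 of 15 interferon-gamma-responsive GTPases rose, and another signal could have held class II down. The class II values therefore cannot decide whether interferon gamma was the whole source of the response. Ciita, the class II regulator, had 14 counts in all controls and 13 after co-culture. T cell RNA in the microglial wells is argued against as the source: 6 T cell receptor complex genes summed to 0.261 CPM, 0.1% of the median rise of 260 CPM of the list. Ifnb1 had 0 counts in the controls and 8 after co-culture, at 0, 5 and 3 per library. Ciita and Ifnb1 were named after the results were seen. The source of the response stays open. Type I interferon was not tested as one, and the samples analysed here include no blocked or deficient interferon receptor and no Tregs kept away from brain slices. None is recorded as given a slice-exposed insert without Tregs.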
